A study of Mus musculus with 12 samples.

How the data were processed

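Gene expression was measured in J1, a mouse embryonic stem cell (ESC) line, on 12 single-colour Agilent arrays. Cells were infected with a lentivirus carrying a non-targeting short hairpin RNA (shNT) or one against Ino80 (shIno80), and RNA was taken 2, 4 or 6 days later, which the series design gives as 48, 96 and 144 hours. The series design calls this an infection, while the sample descriptions speak of transfection. Each of the 6 groups held 2 arrays, which the series design lists as biological replicates. Nothing in the sources used here says how the 2 cultures of a group were made, so p-values measure the spread between these samples, part of which may be technical.

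The deposited scanner files hold intensities per spot from Agilent Feature Extraction 9.5.3.1 with 1 channel, per the file headers. The labels name the dye Cy5, but the files hold green columns only. The processed intensity had been background-subtracted and detrended within each array, with low spots replaced by a surrogate value, per the file headers, and was not scaled between arrays. The deposited value table holds log2 values. Each of its columns equalled the mean spot intensity of 1 scanner file times 1 factor for that array, within a relative tolerance of 1e-06, with no background subtraction and no centring per gene. How those factors were chosen is not given in the sources used here. The column medians of this table on the log2 scale were 7.30 and 7.22 for shNT at day 2, 7.34 and 7.27 for shIno80 at day 2, 7.26 and 7.24 for shNT at day 4, 7.32 and 7.36 for shIno80 at day 4, 7.29 and 7.23 for shNT at day 6, and 7.47 and 7.42 for shIno80 at day 6.

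The match of value table to scanner files showed that the 2 deposited records tie 6 of the 12 arrays to different samples. On each of the 3 slides, the arrays at positions 2 and 3 are exchanged between shNT and shIno80. Results are given with the samples as the value table's columns name them. The alternative, with samples as the scanner files are attached to them, is given beside the counts. This choice was made after the correlations between arrays and the Ino80 probes had been seen, so the lower Ino80 signal in the shIno80 samples is not independent evidence of the knockdown.

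Values were log2 of the processed intensity minus each array's 75th percentile over non-control probes. Spots marked as non-uniform or as population outliers were left out, and the spots of a probe were averaged. Of 41174 probes, 125 were dropped for such marks, and 28657 were kept as well above background on both arrays of at least 1 group. A gene was represented by its probe with the highest mean over the 12 arrays, which left 19184 genes, of which 14960 had a name other than a clone, RIKEN, Gm or LOC number or an accession. Probe accessions were looked up in a RefSeq gene table of assembly GRCm38.p6. This named 22951 probes by accession, 6659 by symbol and 3109 by an older symbol, and 8455 kept the name in the file. No genome was used, and no coordinates are given. Probes of near-identical gene copies cannot be told apart, which concerns the Usp17l and Zscan4 families in particular.

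Depth on an array is its signal over background. Between 61.85% and 69.16% of probes were well above background on each array, 0 to 4 probes were saturated, and the 75th percentile of the processed intensity lay between 1162 and 1643. The number of arrays limits the precision. Whether a gene was well above background was read from its reported probe. Where it was not on any array of a group, its change is given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the gene's own signal.

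A linear model with 1 mean for each of the 6 groups was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, 6 residual and 2.19 prior degrees of freedom) in R 4.3.3. Contrasts were shIno80 minus shNT at each day, the mean of these 3 differences, the differences between days of these differences, and shNT at days 4 and 6 against day 2. P-values were adjusted by Benjamini-Hochberg over genes within a contrast, with a threshold of 0.05. Each slide, scanned in 1 scan, held the 4 arrays of 1 day. Slide effects cancel within a day and, if additive, in the differences between days, but not in the shNT time contrasts, where slide and day cannot be told apart. The position on the slide goes with the group under either record, so position and group cannot be told apart.

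In all, 21 gene lists with 404 members were tested with limma's camera (inter-gene correlation 0.01), adjusted over the lists within a day. Of the members, 395 were on the array and 370 were kept. Camera with an estimated correlation and fry were run beside it. The lists, tests, contrasts, alternatives and the rule for naming genes were fixed before the data were examined. The rule takes 13 genes always (Ino80, Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42, Cdx2, Gata4, Gata6, Fgf5, Brachyury and Cdkn1a). It adds the 10 largest rises and 10 largest falls past the threshold, with groups that do not overlap, at each day and over days, the 5 largest each way for the other contrasts, and the 2 largest each way in each list and day, or the member with the largest change if none passed. Names were taken from the top of these orders. The orders are by fitted log2 fold change, so a gene given by a bound can stand above one with a larger measured fold. The alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50 followed by quantile normalization, no filter on dim probes, a filter for probes well above background on all 12 arrays, the mean of a gene's probes, the value table, a robust trended variance, a replicate block, leaving out each array, a fold threshold, and the 4 arrays of a day alone. The scanner file attachments, and the 4 arrays of a day alone for the gene lists, were added after seeing the data.

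The fit was tested on simulated data made from the real means and residual spreads of the 19184 genes. For each day, 67 genes were changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold, which gave 110, 100 and 125 calls at days 2, 4 and 6. The real data gave many more calls, and more calls loosen the adjusted threshold. The rates below therefore do not give the sensitivity of the real contrasts. Of the 2-fold changes put in, 53.7% were recovered at day 2, 49.3% at day 4 and 61.2% at day 6. Of the 4-fold changes, 83.3%, 80.3% and 89.4% were recovered, and of the 1.5-fold changes 17.9%, 16.4% and 23.9%. For the mean over days, 77.6% of 2-fold changes were recovered. Between 2.9% and 7.2% of the calls fell on unchanged genes over the 9 contrasts. A simulation with no change gave 0 calls in each of them. The simulated noise was drawn independently for each gene and array, so these rates need not hold where genes or arrays vary together.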

Results

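The experiment asked what happens over time to gene expression in mouse ESCs when Ino80, the ATPase of the INO80 chromatin remodelling complex, is knocked down. RNA from J1 cells, a mouse ESC line, was hybridised to 12 arrays, 2 for each of shNT and shIno80 at days 2, 4 and 6 after lentiviral infection. The 75th percentile of the processed intensity lay between 1162 and 1643 over the arrays, and 61.85% to 69.16% of probes were well above background. The 2 deposited records did not place 6 of the 12 arrays under the same samples. With samples taken from the value table, the 2 arrays of a group correlated at r = 0.9905 to 0.9941 across probes, above every other pair of arrays. With samples taken from the scanner file attachments, arrays of a group correlated at 0.9476 to 0.987. All values below use the value table's samples unless the attachments are named.

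Ino80 was lower in the shIno80 arrays on all 3 days, at 25.2% of the shNT signal at day 2, 20.3% at day 4 and 23.5% at day 6 (log2 fold changes −1.99, −2.30 and −2.09, each with SE 0.17; limma adjusted p = 0.000779, 2.55e-05 and 2.62e-05). All 3 kept probes of the gene fell on each day, by 1.95 to 2.66 on the log2 scale. Relative to the 75th percentile of its array, the log2 signal of Ino80 was 2.72 and 2.67 in shNT and 0.56 and 0.85 in shIno80 at day 2. It was 2.26 and 2.16 against −0.29 and 0.12 at day 4, and 1.89 and 2.05 against −0.23 and −0.01 at day 6. Under the scanner file attachments, each group of a day held 1 array with high and 1 with low Ino80 signal, and the log2 fold changes were 0.12, 0.16 and 0.19 (SE 1.32, limma adjusted p = 1, the highest over all alternatives, of which the lowest were 1.26e-05, 1.07e-07 and 2.93e-07).

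**Figure D1:**
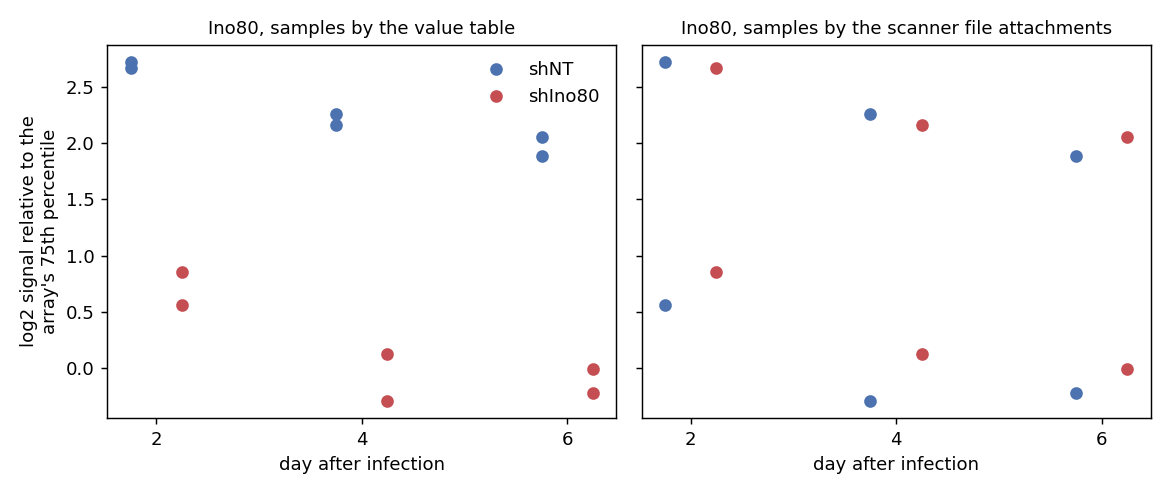
Log2 signal of Ino80 on each of the 12 arrays, relative to the array's 75th percentile, against the day after infection, with each point 1 array. Left, samples as the value table names them, with shNT at 1.89 to 2.72 and shIno80 at −0.29 to 0.85. Right, the same arrays with samples as the scanner files are attached.

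At day 2, fewer genes passed the test than on the later days. In the fit, Prg2 (at least 5.1-fold), Reg3d (at least 3.99-fold) and the adhesion molecule gene Negr1 (at least 2.67-fold) rose most. By their reported probes, Prg2, which encodes eosinophil major basic protein, Reg3d and Negr1 were well above background in shIno80 at day 2. They were so in no other group, and so not in shIno80 at days 4 and 6. Sh3rf2 rose 5.54-fold (log2 fold change 2.47 ± 0.22 SE, n = 2 arrays per group here and below). Trim67 (at least 1.31-fold, seen on 1 shIno80 array), Igsf11 (at least 2.05-fold), Ms4a4d (at least 2.48-fold), Klf14 (at least 2.38-fold) and Sytl4 (at least 1.42-fold, seen on 1 shIno80 array) followed, and the Wnt receptor gene Fzd1 rose 4.78-fold with 1 of the 2 shNT arrays well above background. Among the falls, Rcbtb1 fell 9.45-fold (−3.24 ± 0.21), Gnai3, a G protein alpha subunit gene, 8.42-fold (−3.07 ± 0.17), Ccnc, which encodes cyclin C, 7.76-fold (−2.96 ± 0.16), and both Lonrf2 and Bbx 7.53-fold. Lrrtm1 (at least 5.1-fold) and Rassf9 (at least 4.37-fold) were not well above background in shIno80. Not every probe of these genes moved alike: a second probe did not pass for Ccnc (−0.16), Trim67 (0.46) or Igsf11 (0.31), that of Rcbtb1 fell by 1.02 and those of Bbx fell by 1.98 and by 2.18 on the log2 scale, and that of Ms4a4d was at 3.26. Klf4 fell by 0.97 ± 0.16, Fgf5, a marker of the primed epiblast, by 1.23 ± 0.28 and Cdkn1a, which encodes the cell cycle inhibitor p21, by 0.69 ± 0.17 on the log2 scale (adjusted p = 0.00875, 0.0279 and 0.0325). Nanog (−0.96 ± 0.30), Pou5f1 (−0.32 ± 0.17), Sox2 (−0.35 ± 0.11), Esrrb (−0.31 ± 0.23) and Zfp42 (−0.53 ± 0.15) did not pass the test at this day, with adjusted p between 0.0509 and 0.463. Nor did Cdx2 (−0.38 ± 0.51), Gata4 (−0.47 ± 0.20), Gata6 (−0.84 ± 0.30) or Brachyury (T, 0.08 ± 0.25). With a replicate block, however, Nanog, Pou5f1, Zfp42 and Gata6 passed.

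In all, limma called 2397 of 19184 genes at day 2, with 1206 higher and 1191 lower, and 287 and 351 of them by at least 2-fold. With median scaling 714 were higher and 1030 lower, and with the value table these were 1478 and 1018. Fitted on the 4 arrays of that slide alone, 6 genes passed, all lower. Leaving out an shIno80 array of day 2 left 1168 calls without replicate 1 and 1083 without replicate 2, and with no filter on dim probes there were 1365. With the scanner file attachments limma called 0 genes at day 2, with 586 at an unadjusted p under 0.05.

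By day 4, most measured pluripotency genes had fallen and most markers of trophectoderm, the lineage that forms the placenta, had risen. Nanog fell 13-fold (−3.71 ± 0.30), Klf4 8.79-fold (−3.14 ± 0.16), Esrrb 7.32-fold (−2.87 ± 0.23), Zfp42 4.04-fold (−2.01 ± 0.15), Sox2 2.32-fold (−1.21 ± 0.11) and Pou5f1 2.19-fold (−1.13 ± 0.17). Hand1, a trophoblast transcription factor gene, rose 21.8-fold (4.44 ± 0.13) and Cdx2 4.68-fold (2.23 ± 0.51). By fitted log2 fold change, the largest rises were in Csf1 (at least 68.7-fold), which encodes the macrophage growth factor M-CSF, Synpo2l (60.4-fold) and Pax1 (40.1-fold). Next came Eya4 (at least 25.4-fold), the chemokine gene Ccl20 (at least 19.3-fold) and Mal (at least 12.5-fold). Thrombospondin 1 (Thbs1, 25.9-fold), the TGF-beta receptor gene Tgfbr2 (25.7-fold) and the prostaglandin transporter gene Slco2a1 (22.2-fold) followed. Lrrc34 fell 31.2-fold, Oas1a, an interferon-induced oligoadenylate synthetase gene, 28.4-fold with 1 of 2 shIno80 arrays well above background, Rassf9 24.6-fold, and Inhbb, a subunit gene of activin B, 22.5-fold. Accsl (17.7-fold), the netrin gene Ntn1 (16.1-fold), Hhip (at least 4.69-fold) and Myo1f (15.2-fold) also fell, as did Tgtp1 (at least 6.13-fold) and Mcf2 (15.9-fold, well above background on 1 of 2 shIno80 arrays). Other probes gave smaller changes on the log2 scale for Synpo2l (3.46), Pax1 (2.26, not passing), Eya4 (2.46 and 3.16), Mal (3.95), Thbs1 (3.71), Tgfbr2 (1.61), Slco2a1 (0.91), Inhbb (−1.13), Ntn1 (−2.60), Gata6 (−0.998) and Tgtp1 (−0.37, not passing). Gata6, of the primitive endoderm, was 5.79-fold lower in shIno80 than in shNT. Its mean log2 signal in shIno80 was −4.47 at day 2 and −4.53 at day 4, while in shNT it went from −3.62 to −1.99. Fgf5 rose 2.77-fold, Brachyury (T) rose at least 1.55-fold and Cdkn1a rose 1.46-fold (0.54 ± 0.17). Gata4 did not pass (−0.23 ± 0.20, limma adjusted p = 0.387).

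Limma called 8107 genes at day 4, with 4018 higher and 4089 lower, and 8444 on the 4 arrays of that slide alone. With median scaling 39.2% of the calls were higher instead of 49.6%, and the median over all genes was −0.20 instead of −0.05 on the log2 scale. With the scanner file attachments limma called 0 genes at day 4, with 166 at an unadjusted p under 0.05.

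At day 6, Eya4, a transcriptional coactivator gene, rose at least 43.9-fold, Cryab, a small heat shock protein gene, rose 80.8-fold (6.34 ± 0.16) and Csf1 73.8-fold (6.21 ± 0.17). The placental homeobox gene Esx1 rose 60.6-fold (5.92 ± 0.11), Ddn 55.9-fold, Wnt10a 51.9-fold and Limch1, seen on 1 of 2 shNT arrays, 49-fold. Mal (at least 44.2-fold), Ppbp (at least 22.3-fold) and Vgll1 (at least 13-fold) rose from signals not well above background in shNT. Cdx2 was 12.9-fold higher (3.68 ± 0.51), Brachyury (T), of the primitive streak, 3.4-fold higher with 1 of 2 shNT arrays well above background, and Cdkn1a 1.76-fold higher (0.81 ± 0.17). Among the falls were Oas1a (at least 36.7-fold), Pdcl2 (at least 25.8-fold), Srgn (at least 21.1-fold), which encodes the proteoglycan serglycin, Pgc (at least 15.1-fold), Pla2g4e (at least 13.5-fold), Oas1d (at least 7.57-fold) and Adgrd1 (at least 9.3-fold). Slc11a1 and the ribosomal protein paralogue gene Rpl39l each fell 30.5-fold. Other probes gave smaller changes on the log2 scale for Eya4 (4.81 and 3.33), Cryab (4.41), Limch1 (1.20), Pla2g4e (−1.08) and Adgrd1 (−0.84, not passing), and a larger one for Rpl39l (−5.81). Nanog was 6.58-fold lower, Esrrb 5.76-fold, Klf4 3.95-fold, Pou5f1 3.62-fold, Zfp42 3.59-fold and Sox2 3.38-fold. Gata4 (−0.12 ± 0.20), Gata6 (−0.13 ± 0.30) and Fgf5 (−0.23 ± 0.28) did not pass.

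Limma called 9700 genes at day 6, with 4034 higher and 5666 lower, and 9481 on the 4 arrays of that slide alone. With the value table, which differs both in scaling and in having no background subtraction, 62% of the calls were higher instead of 41.6%, and the median over all genes was 0.06 instead of −0.14. With median scaling, which changes the scaling alone, 36.4% were higher and the median was −0.23. With the scanner file attachments limma called 0 genes at day 6, with 374 at an unadjusted p under 0.05.

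**Figure D2:**
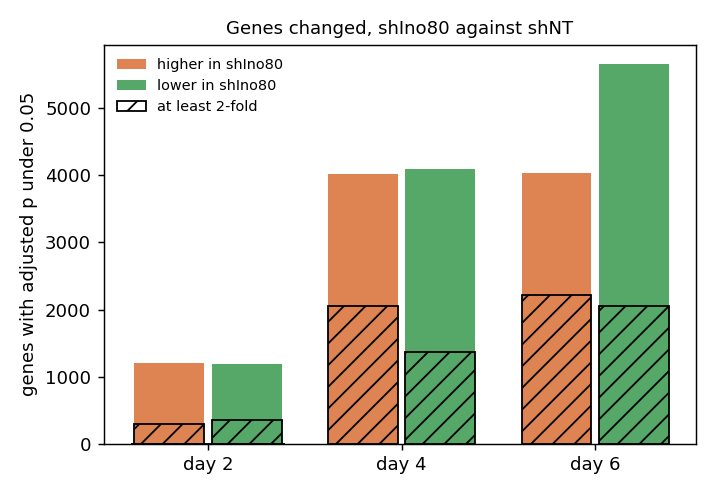
Number of genes with a limma adjusted p under 0.05 for shIno80 against shNT at each day, by direction, with 2 arrays per group. Hatched parts are changes of at least 2-fold, which numbered 287 higher and 351 lower at day 2 and 2216 higher and 2059 lower at day 6.

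Most pluripotency genes were lower from day 4 on. Of 26 measured, 5 fell at day 2, 22 at day 4 and 24 at day 6, and adjusted over the list alone 8, 22 and 24, with median log2 fold changes of −0.35, −1.27 and −1.79 (camera adjusted p = 0.000209, 7.1e-08 and 2.17e-08). With an estimated correlation the adjusted p was 0.792, 0.233 and 0.246. At day 2 the leading falls were in Nr5a2 (3.08-fold), an orphan receptor gene, and Tbx3 (2.27-fold, with a second probe at −1.24 on the log2 scale that did not pass), and at day 6 in Tcl1 (9.57-fold) and Nanog. Dppa3 was the member that rose at days 4 and 6, by 3.25-fold and 1.86-fold.

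**Figure D3:**
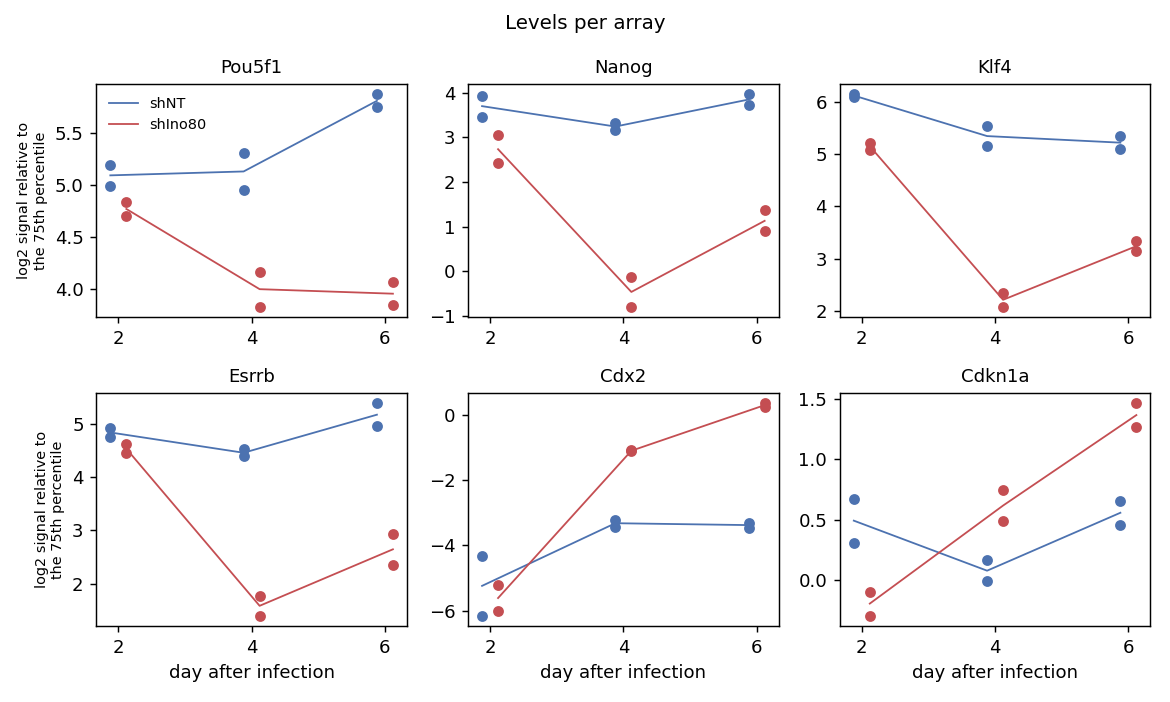
Log2 signal relative to the array's 75th percentile against the day after infection for Pou5f1, Nanog, Klf4, Esrrb, Cdx2 and Cdkn1a, with 1 point per array, lines through the means of the 2 arrays and a separate vertical scale for each gene. Pou5f1, Nanog, Klf4 and Esrrb were lower and Cdx2 and Cdkn1a higher in shIno80 at days 4 and 6, while at day 2 Cdkn1a was lower.

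Of the lineage lists, camera called trophectoderm. Of its 18 measured genes, 2 rose and 2 fell at day 2, 14 rose and 0 fell at day 4, and 15 rose and 1 fell at day 6. Adjusted over the list alone, 2, 15 and 15 rose and 3, 1 and 1 fell. The medians were 0.20, 2.07 and 3.40 (camera adjusted p = 0.582, 1.49e-07 and 3.37e-09; at days 4 and 6 the adjusted p was 0.233 and 0.158 with an estimated correlation). With normexp the medians at days 4 and 6 were 1.34 and 2.10, and with the value table that of day 6 was 2.75. Krt18 rose 21.1-fold at day 4 and Krt7 41.4-fold at day 6, both keratins of simple epithelia, while Tfap2c fell 3.71-fold at day 2 and 2.71-fold at day 6. Markers of fibroblasts, which are used as feeder cells for ESCs, rose on the same days. Of 16 measured, 3, 12 and 12 rose at days 2, 4 and 6 and 1 fell on each day, and adjusted over the list alone 3, 12 and 13 rose (medians 0.15, 1.83 and 1.92; camera adjusted p = 0.253, 8.35e-06 and 4.4e-07; at days 4 and 6 the adjusted p was 0.233 and 0.158 with an estimated correlation). With genes seen in 1 group only set at their bound, the median at day 4 was 1.10. With normexp the medians at days 4 and 6 were 0.64 and 0.81, and from the value table they were 0.90 and 1.30. At day 6 Col1a1 was 14.7-fold and Dcn, seen on 1 of 2 shNT arrays, 14.1-fold higher, and Thy1 fell 2.14-fold, 2.36-fold and 1.6-fold on the 3 days.

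Of 18 primitive endoderm and endoderm genes, 2, 7 and 6 rose and 2, 4 and 3 fell at days 2, 4 and 6 (4, 4 and 3 fell adjusted over the list alone; camera adjusted p = 0.962, 0.334 and 0.142). The type IV collagen genes Col4a2 and Col4a1 rose 12.6-fold and 9.93-fold at day 6, while Lama1 fell 2.56-fold. Of 15 primitive streak and mesoderm genes, 0, 4 and 4 rose and 2, 4 and 5 fell (0, 4 and 5 rose and 3, 5 and 6 fell adjusted over the list alone; camera adjusted p = 0.189, 0.509 and 0.928), with Wnt3 9.39-fold higher and Evx1 3.17-fold lower at day 6. At day 4, 9 of these fell after quantile normalization, 7 with normexp and 6 with median scaling. Of 9 primed epiblast genes, 0, 2 and 1 rose and 2, 4 and 5 fell (3, 4 and 5 fell adjusted over the list alone; camera adjusted p = 0.679, 0.224 and 0.0818), with Foxd3 4.1-fold and Nodal 2.4-fold lower and Pou3f1 1.86-fold higher at day 6. At day 6 camera called this list with the value table (adjusted p = 0.043) and with no filter on dim probes (0.0487), with 0.000131 to 0.276 over the alternatives. Of 13 neural ectoderm genes, 3, 4 and 5 rose and 0, 4 and 6 fell, also adjusted over the list alone (camera adjusted p = 0.679, 0.987 and 0.855). Dlx2 (at least 20.6-fold) and Zic1 (at least 4.85-fold) rose at day 6, while Pax6 (4.18-fold) and Tubb3 (2.83-fold) fell. Of the 8 probes of Ncam1, which fell 2.12-fold at day 4 by its brightest probe, 1 was higher and 2 were lower. Fry called primitive endoderm and endoderm at days 4 and 6 (up, fry adjusted p = 0.049 and 0.00215). It also called primed epiblast on these days (down, 0.000478 and 0.000131) and primitive streak and mesoderm at day 2 (down, 0.0471). Neural ectoderm did not pass with fry on any day.

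Of 19 measured Hox genes, 1, 6 and 8 rose and 0 fell on each day, also adjusted over the list alone, with medians of −0.03, 0.07 and 0.16, or −0.03, 0.02 and 0.51 with genes seen in 1 group only set at their bound (camera adjusted p = 0.719, 0.0691 and 0.00256, the last with adjusted p = 0.276 with an estimated correlation). The rise at day 2 was that of Hoxd8, which was not well above background on any array of that day, so its size is not known. The day 4 median was below 0 with quantile normalization, median scaling and normexp. Median scaling shifts all genes alike (all-gene median −0.195), and the list's median relative to all genes stayed at 0.12 with it. Hoxd8 and Hoxd9 were at least 5.43-fold and at least 3.89-fold higher at day 6, and the list did not pass among genes well above background on all 12 arrays (camera adjusted p = 0.231, with 8.01e-05 to 0.276 over the alternatives). After quantile normalization 1 Hox gene fell at days 4 and 6. At day 4 camera called the list with median scaling (adjusted p = 0.0475) and with the mean of a gene's probes (0.0313), with 0.00175 to 0.564 over the alternatives. Of 14 germline genes, 0, 6 and 7 rose and 2, 2 and 4 fell (1, 6 and 7 rose and 3, 3 and 4 fell adjusted over the list alone; camera adjusted p = 0.679, 0.138 and 0.201). Fry called the germline list at day 4 (up, fry adjusted p = 0.0254). Rhox6 rose 7.34-fold at day 6, while Stra8, a gene of meiotic entry, fell 8.55-fold. Genes of the 2-cell-like state, a transient totipotent-like condition of some ESCs, rose in 0, 6 and 5 of 6 measured members, and in 0, 6 and 6 adjusted over the list alone, with medians of 0.77, 2.63 and 2.03 (camera adjusted p = 0.221, 0.00313 and 0.00526; at days 4 and 6 the adjusted p was 0.386 and 0.344 with an estimated correlation). Zfp352 was 8.25-fold higher at day 4 and 9.86-fold at day 6. The Usp17l members of this list share near-identical sequence.

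The 4 lists of proliferation and energy metabolism had medians below 0 and were called by camera at days 4 and 6, with the preset correlation. Of 20 DNA replication genes, 1, 17 and 16 fell and 0, 1 and 1 rose, with 4, 17 and 16 falls adjusted over the list alone and medians of −0.20, −0.75 and −0.93 (camera adjusted p = 0.0326, 6.28e-06 and 5.16e-05; adjusted p = 0.845, 0.302 and 0.276 with an estimated correlation). At day 2 the median was −0.12 both after quantile normalization and with normexp. Pola1, the catalytic subunit gene of DNA polymerase alpha, fell 4.76-fold and Mcm10 4.8-fold at day 6, and Ccne2, which encodes cyclin E2, rose 1.61-fold. Of 20 mitosis genes, 0, 8 and 9 fell and 0 rose, and adjusted over the list alone 0, 7 and 9 fell (medians −0.01, −0.31 and −0.43; camera adjusted p = 0.679, 0.019 and 0.0339; at days 4 and 6 the adjusted p was 0.409 and 0.419 with an estimated correlation). At day 4, 3 mitosis genes fell after quantile normalization, at day 6, 5 fell with the value table, and 3 rose on both days with normexp and at day 6 with the value table. The medians at days 4 and 6 were −0.17 and −0.22 after quantile normalization and −0.18 and −0.19 with normexp, and that of day 6 was −0.19 in the value table. Of 20 oxidative phosphorylation genes, 1, 12 and 16 fell and 0 rose, also adjusted over the list alone, with medians of −0.17, −0.41 and −0.60 (camera adjusted p = 0.0342, 0.00461 and 0.001; adjusted p = 0.845, 0.586 and 0.425 with an estimated correlation). After quantile normalization the medians were −0.08, −0.25 and −0.34, with normexp −0.08, −0.26 and −0.35, and that of day 6 was −0.33 in the value table. Of 21 genes of glycolysis and hypoxia, 1, 11 and 14 fell and 1, 1 and 2 rose, with 1, 12 and 14 falls adjusted over the list alone (medians −0.09, −0.39 and −0.69; camera adjusted p = 0.45, 0.00754 and 0.00408; at days 4 and 6 the adjusted p was 0.409 and 0.363 with an estimated correlation). With normexp 7 fell at day 4 and the medians at days 4 and 6 were −0.18 and −0.39, while after quantile normalization that of day 4 was −0.26 and in the value table that of day 6 was −0.43. Pfkp fell 4.5-fold at day 6 and the glucose transporter genes Slc2a3 and Slc2a1 rose 1.65-fold and 1.47-fold, with smaller changes at a second probe of Pfkp (−1.25 on the log2 scale) and of Slc2a3 (0.18, not passing).

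Of 30 cytosolic ribosomal protein genes, 0, 6 and 24 fell and 0 rose, with 0, 5 and 28 falls adjusted over the list alone (medians −0.10, −0.21 and −0.49; camera adjusted p = 0.114, 0.0124 and 3.19e-05; at days 4 and 6 the adjusted p was 0.609 and 0.437 with an estimated correlation). At day 6, 9 fell after quantile normalization, 12 with normexp and 13 with the value table, and at day 4, 11 fell with median scaling. The day 6 medians were −0.10 with normexp and −0.25 in the value table, and those of day 4 were −0.06 after quantile normalization, −0.07 with normexp and −0.35 with median scaling. After quantile normalization the day 6 median of this list was −0.12 and camera did not call it (adjusted p = 0.122, with 3.9e-07 to 0.437 over the alternatives), nor did it with normexp (0.0987). Quantile normalization and normexp also ended the camera calls for ribosomal proteins at day 4, for mitosis at days 4 and 6, for oxidative phosphorylation and glycolysis at day 4 and for DNA replication and oxidative phosphorylation at day 2. Median scaling and the value table ended those of day 2 too, and the value table that of mitosis at day 6, as did keeping probes well above background on all 12 arrays. On the 4 arrays of each slide alone, camera called 1, 11 and 12 lists at days 2, 4 and 6, without DNA replication and oxidative phosphorylation at day 2 and INO80 subunits at day 6.

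Of 15 immediate early genes, 5, 10 and 9 rose and 1, 3 and 2 fell, with 3, 3 and 2 falls adjusted over the list alone (medians 0.27, 0.94 and 1.03; camera adjusted p = 0.248, 0.00682 and 0.00101; at days 4 and 6 the adjusted p was 0.409 and 0.276 with an estimated correlation). Ccn1, a matricellular protein gene, rose 3.57-fold, 12.6-fold and 13.1-fold on the 3 days, while Egr1 fell 2.89-fold at day 4 and 2.13-fold at day 6. Of 23 p53 targets and cell cycle inhibitors, 2, 11 and 11 rose and 5, 3 and 4 fell, with 3, 11 and 11 rises adjusted over the list alone (camera adjusted p = 0.9, 0.0863 and 0.00254, the last with adjusted p = 0.419 with an estimated correlation). At day 4, 7 rose with median scaling, and at day 6, 17 rose with the value table. Camera called this list at day 4 after quantile normalization (adjusted p = 0.0301) and with normexp (0.0261), with 0.0219 to 0.609 over the alternatives. Cdkn2a, which encodes cell cycle inhibitors, rose 1.79-fold, 4.02-fold and 5.57-fold and Perp 6.55-fold at day 6, while Bax fell 2.17-fold at day 2 and Gdf15 fell 4.81-fold at day 6.

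Of 19 interferon response genes, 0, 6 and 5 rose and 4, 6 and 5 fell (0, 7 and 5 rose adjusted over the list alone; camera adjusted p = 0.527, 0.749 and 0.644). Ddx58, which encodes the RNA sensor RIG-I, fell 4.23-fold at day 2, Oas2 fell at least 7.95-fold at day 6, and Ifih1 and Usp18 rose at least 7.17-fold and at least 4.49-fold at day 6. Of 18 genes of the unfolded protein and amino acid stress responses, 0, 5 and 3 rose and 3, 4 and 7 fell (1, 5 and 3 rose and 5, 4 and 7 fell adjusted over the list alone; camera adjusted p = 0.348, 0.987 and 0.715), with Atf3 10.6-fold higher and Chac1 3.06-fold lower at day 6. At day 2, 1 of these fell after quantile normalization and with the value table, and 4 with normexp. With each of these settings 2 fell at day 4, and with normexp 5 rose at day 6.

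Of 14 measured INO80 complex subunit genes, 1, 5 and 7 fell and 0, 1 and 0 rose, with 1, 6 and 7 falls adjusted over the list alone (medians −0.08, −0.31 and −0.35; camera adjusted p = 0.189, 0.0167 and 0.0412; at days 4 and 6 the adjusted p was 0.233 and 0.276 with an estimated correlation). Ino80, the target of the hairpin, is one of them and was the 1 that fell at day 2. Camera was not run without it, so these calls in part reflect the knockdown itself. Actl6a fell 1.69-fold at day 4 and 2.08-fold at day 6, when a second probe did not pass (−0.15 on the log2 scale). With median scaling 8 fell at day 4, and at day 6, 4 fell with the value table, where the median was −0.11. After quantile normalization and with normexp camera called this list on neither day, and with median scaling, the value table, the mean of a gene's probes or probes well above background on all 12 arrays not at day 6. Of 16 other chromatin remodelling genes, 2, 1 and 2 rose and 0, 4 and 3 fell (0, 4 and 2 fell adjusted over the list alone; camera adjusted p = 0.779, 0.334 and 0.936). Smarca2, a SWI/SNF ATPase gene, rose 1.8-fold and 2.67-fold at days 2 and 4 and at least 7.5-fold at day 6. Counts adjusted over the list alone that are not given above were the same as those over all genes. The median and mean of a list differed in sign for neural ectoderm on all 3 days, for interferon response at days 4 and 6, and for primitive endoderm, primed epiblast and p53 targets at day 2. They also did so for stress responses at day 4, for primitive streak at day 6 and for other remodellers at days 2 and 6.

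**Figure D4:**
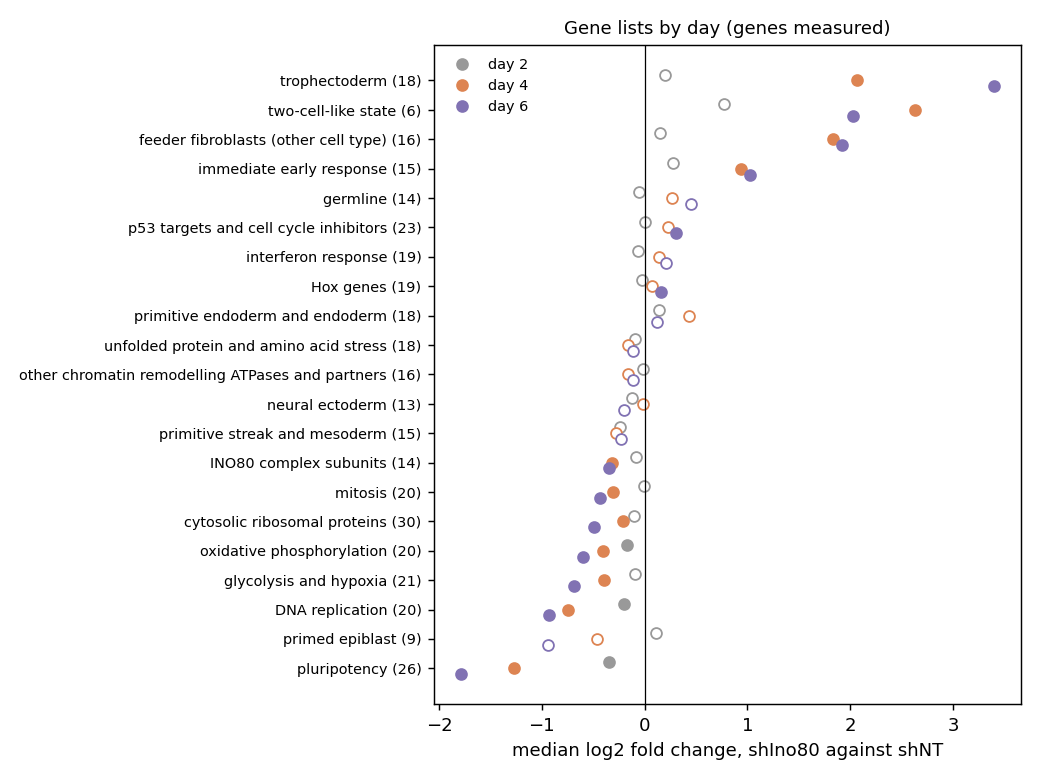
Median log2 fold change of shIno80 against shNT over the measured members of each of the 21 gene lists at days 2, 4 and 6, with the number of measured genes in brackets and 2 arrays per group. Filled points passed camera at an adjusted p under 0.05 with the preset correlation. The trophectoderm medians reach 3.40 and the pluripotency medians −1.79.

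The responses of the days were compared directly. Between days 2 and 4 the response differed for 2940 genes, between days 2 and 6 for 5195, and between days 4 and 6 for 728 (limma interaction contrasts). The falls of Nanog, Klf4, Esrrb, Zfp42 and Sox2 were deeper at day 4 than at day 2, with adjusted p between 0.00104 and 0.00966, and the fall of Pou5f1 was deeper at day 6 than at day 2 (by 1.53 ± 0.24 on the log2 scale, adjusted p = 0.00276). From day 4 to day 6 the fall of Klf4 became smaller (difference 1.15), as did that of Gata6 (2.41), whose second probe did not pass (0.76). Cdkn1a and Fgf5 were lower at day 2 and higher at day 4, and these differences passed (1.23 ± 0.23 and 2.70 ± 0.40). Of the largest differences measured in all groups, Cryab gained 6.43 ± 0.23 (4.55 by a second probe) and the actin gene Acta1 5.81 ± 0.50 from day 2 to day 6, Ddn gained 4.29 ± 0.27 from day 4 to day 6, and Lrrc34 lost 4.01 ± 0.33 from day 2 to day 4. The fold of Ino80 itself did not differ between days (adjusted p = 0.442 for days 2 and 4 and 0.789 for days 2 and 6).

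The share of positive differences between days 4 and 6 was 40.8%, but 52.8% with median scaling and 77% with the value table, and between days 2 and 6 it was 41.8%, but 65.3% with the value table. Without single arrays of days 4 or 6, the count for days 4 and 6 was 200 (shNT day 4 replicate 2), 227 (shIno80 day 4 replicate 1), 261 and 263 (shIno80 day 6 replicates 1 and 2), 307 (shNT day 4 replicate 1), 334 (shIno80 day 4 replicate 2) and 350 (shNT day 6 replicate 1). The count for days 2 and 4 was 1474 and 1903 without shIno80 day 4 replicates 2 and 1, 1616 and 1774 without shNT day 4 replicates 1 and 2, and 1845 without shIno80 day 2 replicate 1. With no filter on dim probes the counts were 1855 for days 2 and 4 and 277 for days 4 and 6. With the scanner file attachments limma called 0 genes in each of the 3 differences, with 112, 524 and 286 at an unadjusted p under 0.05.

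Averaged over the 3 days, Synpo2l rose 16.9-fold (4.08 ± 0.19), Sh3rf2 14.8-fold, Thbs1 12.6-fold, Tgfbr2 10.3-fold and Slco2a1 9.97-fold. Nkx6-3 fell 10.3-fold (−3.37 ± 0.16), Slc11a1 10.2-fold, Rcbtb1 9.02-fold, Accsl 8.75-fold, Lrrc34 8.65-fold and Rpl39l 8.61-fold, all well above background on the 12 arrays. Other probes gave smaller log2 changes for Synpo2l (2.60), Thbs1 (2.78), Tgfbr2 (1.48), Slco2a1 (0.82) and Rcbtb1 (−1.20), and a larger one for Rpl39l (−3.89). Eya4, Csf1, Vgll1, Gbp2b and Prss23 also ranked among the largest rises and Rassf9, Oas1a, Srgn and Oas1d among the largest falls, each not well above background on some arrays. Limma called 10828 genes, 5063 higher and 5765 lower. The higher share was 46.8%, but 59.4% with the value table and 36.9% with median scaling. The log2 fold changes of 2 days correlated across genes, which are not independent replicates, at Pearson's r = 0.526 for days 2 and 4, 0.415 for days 2 and 6 and 0.817 for days 4 and 6 (Spearman's rho 0.556, 0.454 and 0.795). The days share no arrays. At days 4 and 6, 3068 genes were higher on both days, where independent lists would share 844.9, and 3597 were lower on both, against 1208. Of all genes, 747 were higher and 884 lower on each of the 3 days. With the attachments, limma called 0 genes on average over days, with 238 at an unadjusted p under 0.05, and the correlations were 0.213, −0.105 and −0.06.

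Control cells changed with time as well, although day and slide cannot be told apart here. In shNT cells Foxa2, an endoderm transcription factor gene, rose 11.5-fold from day 2 to day 4, Aadac rose 16.7-fold with 1 of 2 day 2 arrays well above background, and Prom2, Trim67 and Hs3st2 rose at least 6.63-fold, at least 4.66-fold and at least 4.22-fold. A2m fell 16-fold, Kif12 at least 7.86-fold, Orly at least 5-fold and the inhibin alpha gene Inha at least 4.13-fold. By day 6, Aire, the autoimmune regulator gene, was 9.72-fold lower (−3.28 ± 0.22), Trem2, Dock10 and Abcc2 at least 13.7-fold, at least 4.63-fold and at least 4.54-fold lower, and Gbp2 21.4-fold and Slc39a8 30.2-fold higher with 1 of 2 day 2 arrays well above background. The guanylate-binding protein gene Gbp2b rose at least 7.64-fold, Trim67 at least 9.05-fold and Slc30a3 at least 11.1-fold. Lrrtm1, which was lower in shIno80 at day 2, was well above background in shNT at day 2 and in no other group, and fell at least 5.33-fold in shNT from day 2 to day 4. Of the pluripotency factors, Klf4 fell by 0.78 at day 4 and 0.90 at day 6 and Pou5f1 rose by 0.72 ± 0.17 at day 6, while Nanog, Sox2, Esrrb and Zfp42 did not pass at either time, although a second probe of Esrrb fell by 1.13 at day 6. A second probe did not pass for Prom2 (−0.25), A2m (−1.15), Kif12 (0.49) or Trim67 (0.98) at day 4, nor for Trim67 (0.83) or Slc39a8 (1.68) at day 6, and that of Trem2 fell by 2.64. Ino80 fell by 0.73 ± 0.17 by day 6 (limma adjusted p = 0.0166, and −1.53 by a second probe). Gata6 rose 3.1-fold by day 4 and 2.24-fold by day 6, with a second probe that did not pass (0.67 and 0.57 on the log2 scale). Cdx2 rose 3.79-fold by day 4 and 3.64-fold by day 6, with 1 of 2 day 2 arrays well above background.

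Limma called 2754 genes for shNT at day 4 against day 2, with 1464 higher and 1290 lower, and 4364 at day 6 against day 2, with 2240 higher and 2124 lower. With the value table, at day 4, 1913 were higher and 1240 lower, and 2803 and 1833 at day 6. The day 4 count was 1240 and 4356 without day 2 replicates 1 and 2, 1059 and 1070 without day 4 replicates 1 and 2, and 1809 with no filter on dim probes. The day 6 count was 2675 and 2654 without day 6 replicates 1 and 2. With the attachments, which put other arrays into shNT, the counts were 84 and 68.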

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

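All tests of explanations here, except the splits of the samples, were chosen after the results were seen.

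The responses to shIno80 at 2 days were compared by the interaction contrasts of the fit, and each result of this paragraph differed between days at an adjusted p under 0.05. Between days 2 and 4 the response differed for 2940 genes, with differences on the log2 scale (day 4 minus day 2) of −2.74 for Nanog, −0.87 for Sox2, −2.17 for Klf4, −2.57 for Esrrb, −1.48 for Zfp42, 2.60 for Cdx2, −1.69 for Gata6, 2.70 for Fgf5, 1.23 for Cdkn1a, −4.01 for Lrrc34 and −3.71 for Oas1a. Between days 2 and 6 it differed for 5195 genes, with −1.53 for Pou5f1, −1.75 for Nanog, −1.41 for Sox2, −1.01 for Klf4, −2.22 for Esrrb, −1.31 for Zfp42, 4.06 for Cdx2, 1.69 for Brachyury (T), 1.502 for Cdkn1a, 6.42 for Cryab and 5.81 for Acta1. Between days 4 and 6 it differed for 728 genes, with 1.15 for Klf4, 2.41 for Gata6 and 4.29 for Ddn. A second probe of Gata6 did not pass in either difference (−0.46 and 0.76). Oas1a was well above background on 1 of the 2 shIno80 arrays at day 4, and Cdx2 on 1 array of each group at day 2. Brachyury was not well above background on any shIno80 array at day 2, so its difference is a fitted value.

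Other splits of the samples were run for the mean over days. Of 108 distinct splits of the arrays within days, 100 were drawn, and 1 of them, the real one, called as many as 10828 genes, so chance can be excluded only for labels taken as given. These labels were chosen from 2 records after the correlations between arrays were seen, which favours a split that puts like arrays together. The highest of the others called 9774 and kept the real labels on 2 of the 3 days, but another such split called 5. The split given by the scanner file attachments called 0 genes with limma, against 238 at an unadjusted p under 0.05.

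The 2 deposited records place 6 of the 12 arrays under different samples, and on each slide an array of each group is out of place. One candidate explanation is that the scanner file attachments are right and that the cultures of replicates 1 and 2 differed by batch. Ino80 ranked 56 of 19184 among the falls at day 2 by the value table, 197 at day 4 and 431 at day 6. The other is that the value table is right, and the lowest correlation within a group was 0.9905 by it, against 0.987 as the highest by the attachments. These values prompted the choice of record, and the correlations are no test of it. If the hairpin lowers Ino80 RNA, however, the Ino80 signals of the 6 exchanged arrays argue against the attachments. Those that the attachments call shNT were at 0.564, −0.295 and −0.225 on the log2 scale at days 2, 4 and 6. Those they call shIno80 were at 2.668, 2.158 and 2.052. How the exchange arose is not given in the sources used here. Array position goes with group under both records, and no biological explanation was tested.

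Most fibroblast markers rose in shIno80 at days 4 and 6. More feeder fibroblasts in the shIno80 cultures may account for this, although nothing in the labels names feeder cells. Of the 18 listed markers 12 rose at day 6, 1 fell, 3 did not pass and 2, Postn and Fap, were not well above background on any array of that day. The prediction for more feeder fibroblasts, that all listed markers rise at day 6, was therefore not met. A marker can rise and still miss the threshold, and Postn and Fap were too dim to test, so this decides nothing about feeder cells. The 3 that did not pass were Lum (1.56 on the log2 scale), Prrx1 (0.17) and Mmp2 (0.32). Lum was well above background on 2 shIno80 arrays and 0 shNT arrays of day 6. Col1a1 rose by 3.88 on the log2 scale, Col1a2 by 1.92 and Col3a1 by 1.12, Thy1 fell by 0.68, and 11 of the 18 were well above background on both shNT arrays of day 6, while 0 were in another list. Without a fibroblast profile on this array a share cannot be computed, so other cells and a change of the ESCs after knockdown, which was not tested, cannot be told apart.

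At day 2, 17 genes other than Ino80 were lower by 4-fold or more while well above background on all 4 arrays of that day. Among them were Rcbtb1, Gnai3, Ccnc, Bbx and Ccnd2, of which Ccnd2 falls outside the naming rule and was chosen after its values were seen. The 4-fold cutoff by itself puts all 17 past the reported probe of Ino80 (3.96-fold). By its other probes Ino80 fell 4.6-fold and 5.12-fold. Of the genes with several probes, another probe was lower too in 7 of 8, which argues against faulty single probes for the direction of these falls. For Ccnc it was at −0.16 and did not pass. The size of the falls was not tested this way. On the log2 scale another probe of Rcbtb1 fell by 1.02 against 3.24, and another of Ddx58 by 2.89 against 2.08. The 9 genes with 1 probe stay untested. The shRNA could also act on other transcripts, whose falls would be complete at day 2. Their median change from day 2 to day 6 was 0.56, against −0.23 for the other 1118 genes lower at day 2, with 8 falls smaller and 2 deeper past the threshold (Nkx6-3 by −2.20 and Abraxas1, chosen after its values were seen, by −0.52), but genes picked for large early falls tend to shrink, and the hairpin sequence was not used here. Off-target action and an early effect of low Ino80 therefore cannot be told apart.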

How the results depend on the processing

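Of the alternatives, the scanner file attachments and, for gene lists, the 4 arrays of a day alone were chosen after seeing the data. Of the 355 named gene values past the threshold, 346 kept their direction and side of it with quantile normalization and with median scaling, 340 with normexp, 341 with the value table, 344 with the mean of probes, 352 with the robust trended variance and 317 with no filter, and 0 turned. Of 246 daily values, 184 stayed past the threshold on the 4 arrays of that day alone. Except where stated, the cause of a change was not tested. What limits genes at low signal is the background: a fall into it gives only a bound.

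With the scanner file attachments, which put arrays of high and low Ino80 signal into each group, limma called 0 genes at days 2, 4 and 6, on average and in the 3 differences between days, against 586, 166, 374, 238, 112, 524 and 286 at an unadjusted p under 0.05, and 84 and 68 for shNT at days 4 and 6 against day 2. Ino80 changed sign (0.117, 0.156 and 0.19), correlations of daily responses were 0.213 (days 2 and 4), −0.105 and −0.06, and 1, 0 and 2 lists were called. Of 246 named values 121 kept their sign and 0 were called.

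With no filter, which tests more genes, the counts were 1365 (day 2), 1855 (days 2 and 4), 277 (days 4 and 6) and 1809 (shNT day 4). A change of at least 2-fold, which takes fewer genes by construction, left 638, 3424 and 4275 at days 2, 4 and 6, 2586 on average, 1688 (days 2 and 4), 2828 (days 2 and 6), 1020 and 1563 (shNT days 4 and 6). The 4 arrays of day 2 alone gave 6 genes. Normexp gave 1515 for days 4 and 6.

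Same-numbered replicates shared deviations at r = 0.296, 0.117 and 0.083 on days 2, 4 and 6, which is not over 0.1 on every day. Pairing by number was therefore not taken as shown, but these values do not exclude it. The replicate block gave 3827 genes at day 2, 1328 for days 4 and 6 and 5 lists at day 2, and left the other counts within 1.5 times (9620 at day 4, 11094 at day 6). Of 55 named gene values that did not pass, 12 passed with it, among them Nanog, Pou5f1, Zfp42 and Gata6 at day 2, and of the 355 that passed 346 stayed past the threshold.

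The correlation of days 2 and 4 (0.526) was 0.623 with normexp, 0.373 with no filter, 0.63 with probes above background on all 12 arrays and 0.615 with the value table. That of days 4 and 6 (0.817) was 0.876, 0.697, 0.872 and 0.869, and that of days 2 and 6 (0.415) 0.297 with no filter.

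Of 21 lists camera called 3, 11 and 13 at days 2, 4 and 6. At day 2, 1 was called with quantile normalization, median scaling, normexp, the value table or that day's arrays alone. At day 4, 7 were called with quantile normalization or normexp and 17 with fry. With an estimated correlation 0 were called on each day. The interferon list at day 6 (median 0.207) turned under fry, whose direction was down (adjusted p = 0.00309, with up to 0.957 over the alternatives).

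Leaving out single arrays, with the lone array taken to vary like the others, gave 1083 to 2003 genes at day 2, 5929 to 8697 at day 4, 7723 to 10233 at day 6, 9787 to 10877 on average, 1474 to 2795 for days 2 and 4, 3692 to 5179 for days 2 and 6, 200 to 867 for days 4 and 6, 1059 to 4356 for shNT at day 4 and 2654 to 4180 at day 6. The fold of Ino80 stayed between −2.132 and −1.842, −2.505 and −2.089, and −2.195 and −1.979, correlations between 0.444 and 0.526, 0.324 and 0.434, and 0.786 and 0.817, and lists called between 1 and 5 (5 and 1 without shNT day 2 replicates 1 and 2), 9 and 12, and 11 and 14.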

Other observations

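The guanylate-binding protein gene Gbp2b was among the largest rises on average over days, with 9 of 12 arrays well above background, and it also rose in shNT cells by day 6 (at least 7.64-fold). Of 19 interferon response genes, 5 rose and 5 fell at day 6 and the list was not called (camera adjusted p = 0.644). No test of an explanation was run for these genes.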
